A study of Saccharomyces cerevisiae with 21 samples.

How the data were processed

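Total RNA was collected from BY4743, a diploid laboratory strain of Saccharomyces cerevisiae in which URA3, LEU2 and HIS3 are deleted, over a cycle of drying and rehydration. Per the labels, cells were grown in YPD (a rich glucose medium) at 30 °C to an absorbance of 0.8 at A600. They were moved to YPD diluted 1:20 and dried in 9 cm dishes at 22 to 25 °C under a controlled atmosphere. Later they were given 1:20 YPD again. There were 7 time points with 3 samples each, one array per sample. The 21 samples were assigned to their time points from their titles.

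The deposited table holds intensities, one linear probe set signal per array of the Affymetrix YG_S98 chip, which per the labels came from cRNA hybridization, a scan and the GeneChip expression software with a Wilcoxon signed-rank step. The labels also name a linear mixed model of 2 steps without its terms, and whether the deposited signals precede that model is not given in the sources used here. The 2% trimmed mean of each array lay between 500.2 and 500.6, so the table was taken as already scaled by the authors and was used as deposited. Every change is therefore relative to the scaled signal of its array, not an amount of RNA per cell. The per-array run records, which per the file headers give the chip type and the days of hybridization and scanning, served only to group arrays by scan day.

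Of the 9335 probe sets in the table, 60 chip controls were left out and 9275 were tested. Values under 2.8, the 5th percentile of all positive values, were set to 2.8 before log2 was taken. This floor held 4.99% of values, and 88 values in the table were at or under 0. A linear model with one mean per time point was fitted to all 21 arrays with limma, and variances were moderated by eBayes (residual degrees of freedom 14, prior degrees of freedom 1.53). The 9 comparisons and a moderated F test over the 7 time points were adjusted by the Benjamini-Hochberg method, and a probe set counted as changed at an adjusted p under 0.05. No unit other than the log2 of the deposited intensity entered these tests.

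Probe sets were named through the platform annotation and the RefSeq gene table (assembly R64, used for names only). One gene was listed for 6504 probe sets, several for 328 and none for 2443, and all 6504 were matched by gene identifier, giving 5656 distinct genes. Of the tested probe sets, 1730 carry a suffix that marks possible cross-hybridization. The genes named in the text follow a rule fixed in advance: probe sets with 1 standard gene name and no such suffix, an adjusted p under 0.05 and no overlap between the 3 arrays of one group and the 3 of the other. The 12 largest rises and 12 largest falls were taken for 18 h of drying against control and for 360 min of rehydration against dry, and 5 each way for the other comparisons. Named whatever their values were HSP12, HSP26, HSP104, TPS1, TPS2, SIP18, GRE1, STF2, CTT1, ICL1, MLS1, PCK1, FBP1, POX1, ACT1, URA3, LEU2 and HIS3, and up to 4 members of each gene list with the smallest adjusted p could serve as its examples.

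Background was set at a signal of 29.6, the 95th percentile of 19 control probe sets for mouse genes and unspiked bacterial genes over all arrays. Where all 3 arrays of one group were at or below it, the change is given as "at least N-fold", the brighter group's mean over that level, and no fold is given where both groups were at background. Where only the mean of a group was below it, signals are given. A gene with several probe sets stands in the lists as its brightest one, while the rule for named genes takes each probe set by itself.

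The 30 gene lists were fixed before the data were examined, as were the tests, the rule for named genes and the alternatives not described as added later. Each list was tested against all other probe sets with limma's camera (preset inter-gene correlation 0.01), adjusted over the 270 tests of 30 lists in 9 comparisons, and again with a correlation estimated from the data. Called lists also have the number of other settings, of 7 to 9 per comparison, in which the call held. Members are counted as rose, fell or did not pass over all probe sets tested, and again adjusted over the list alone.

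Alternatives were quantile normalization, median centring, no floor, a floor at the 20th percentile, log2(value + 50), leaving out probe sets with a mean in the lowest 25%, a fit with only the 2 groups compared, an intensity trend in eBayes, the replicate number or the scan day as a block, a change of at least 2-fold, and leaving out each array in turn. Arrays were scanned on 4 days. Day 1 held the 3 control arrays and replicate 2 of 18 h, day 2 the other 18 h arrays, the dry arrays and those of 15 and 45 min, day 3 replicates 1 and 3 of 90 min and all of 360 min, and day 4 replicate 2 of 90 min. No 2 arrays held the same values, with at most 0.900% of values equal in any of 210 pairs.

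The fit was tested on simulated data with the spread of these arrays, with 200 of 9275 probe sets changed between 18 h of drying and control. It recovered 60% of 2-fold and 91% of 4-fold changes, made 6 false calls among 157, and made 0 calls in an unchanged contrast. Software was R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9. The number of arrays limits the precision, and 3 arrays against 3 cannot give an exact two-sided permutation p under 0.1.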

Results

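Gene expression was measured in a diploid yeast strain, BY4743, before drying, while drying, in the dry state and after water was returned. The 21 arrays covered 7 time points with 3 samples each. These were a control taken before drying, 18 h of drying (50% dry per the sample titles), the dry state after 42 h of drying and 72 h at 20% relative humidity, and 15, 45, 90 and 360 min of rehydration. Signals are in the units of the deposited table and are given as mean ± SD (n = 3), changes as log2 ± SE from the fit, and p-values are limma's, adjusted. The labels do not say whether replicates came from separate cultures, so these p-values measure the spread between these samples, which may be technical. On each array 78.6% to 81.4% of probe sets were above background, and the number of arrays limits the precision. For each gene list called in a comparison, and for all lists at 18 h against control, the text gives how many members rose or fell, the rest not having passed the test, and the count adjusted over the list alone where it differs. A list call that is lost with a correlation estimated from the data is given with that p, and the other calls hold.

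Signals differed among the 7 time points for 7813 of 9275 probe sets (84.2%, moderated F test). Across probe sets, which are not independent replicates, arrays of one time point correlated at 0.983 to 0.995. The first principal component, with 49.7% of the variance, set the control arrays apart from the others, and the second, with 17.3%, parted the dry arrays from those at 360 min.

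**Figure D1:**
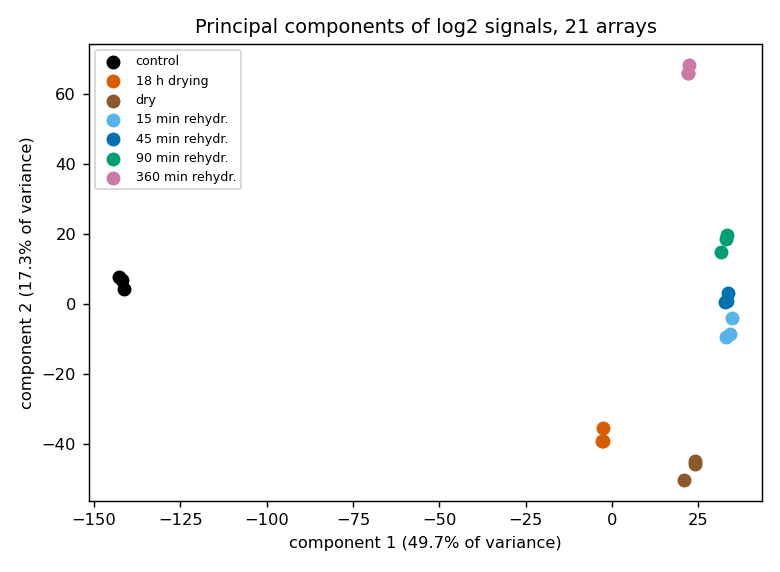
Principal components of the log2 signals, one point per array, with time points told apart by colour. The first axis holds 49.7% and the second 17.3% of the variance, and the 3 arrays of each time point lie near one another.

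The comparison of 18 h of drying with the control asks what changed over the first part of drying. No array held undried cells kept as long in 1:20 YPD at 22 to 25 °C. Medium, temperature and time therefore cannot be told apart from water loss. Transcripts for the use of fatty acids and small carbon compounds rose, as did autophagy genes, and transcripts for building ribosomes, amino acids, sterols and the cell wall fell. Among genes of fatty acid oxidation and the peroxisome, 20 of 21 rose and 1 fell. Their median was 5.28 (log2 change, 4.97 with values under background set to it), with adjusted p = 5.33e-12. CTA1 (YDR256C), the peroxisomal catalase, went from 52.1 ± 6.69 to 6291 ± 308 (log2 6.92 ± 0.10), and POX1, the first enzyme of beta-oxidation, from 61.0 ± 3.19 to 2639.6 ± 50.8. CRC1, the mitochondrial carnitine carrier, was at background in the control and was at least 193-fold higher at 18 h. Of genes of the glyoxylate cycle and gluconeogenesis, 10 of 12 rose and 0 fell. Their median was 5.29 (log2 change), with adjusted p = 2.22e-06. They include isocitrate lyase ICL1 (224 ± 19.2 to 5895 ± 295), malate synthase MLS1 (35.9 ± 10.5 to 4594 ± 251), PCK1, which makes phosphoenolpyruvate (77.5 ± 2.36 to 4556 ± 641), and fructose bisphosphatase FBP1 (62.2 ± 1.63 to 4756 ± 217).

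The hydrophilin gene SIP18 (YMR175W), whose small, water-loving product is linked to survival of drying, was at background in the control and reached 4322 ± 299 at 18 h, at least 146-fold higher. GRE1, another hydrophilin gene, went from 32.2 ± 6.15 to 5156 ± 866. Among general stress genes, 17 of 24 rose and 4 fell. Their median was 1.70 (log2 change), with adjusted p = 1.82e-04, but adjusted p = 0.0657 with an estimated correlation, the call kept in 8 of 9 alternatives. XBP1, a repressor made under stress (487 ± 42.3 to 3742 ± 156), and the phosphogluconate dehydrogenase GND2 (131 ± 14.4 to 2889.9 ± 266) are examples. The cytosolic catalase CTT1 rose by 2.32 ± 0.20, the small heat shock protein HSP26 by 3.82 ± 0.09, the disaggregase HSP104 by 0.73 ± 0.13, STF2 by 1.18 ± 0.12 and the trehalose synthase subunit TPS1 by 0.60 ± 0.09, while HSP12 (-0.39 ± 0.24) and TPS2 (-0.06 ± 0.18) did not pass. Of autophagy genes, 16 of 18 rose and 0 fell (17 and 0 adjusted over the list alone). Their median was 1.58 (log2 change, 1.32 with values under background set to it), with adjusted p = 1.77e-04. The kinase ATG1 is an example (272 ± 23.3 to 1912 ± 137). Among genes repressed by good nitrogen sources, 13 of 19 rose and 2 fell. Their median was 1.35 (log2 change, 0.83 with values under background set to it), with adjusted p = 0.0109, but adjusted p = 0.0890 with an estimated correlation, the call kept in 8 of 9 alternatives. The general amino acid permease GAP1 went from 399 ± 22.4 to 6103 ± 78.8 and the proline permease PUT4 from 84.6 ± 10.3 to 6409 ± 181. Of the nuclear genes of the respiratory chain and ATP synthase, 24 of 30 rose and 1 fell (26 and 1 adjusted over the list alone). Their median was 0.83 (log2 change), with adjusted p = 1.76e-04. QCR9 rose by 2.05 ± 0.10, and the member that fell was cytochrome c, CYC1 (1145 ± 43.3 to 98.2 ± 4.50).

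Of cytosolic ribosomal protein genes, 74 of 80 fell and 6 rose. Their median was -2.49 (log2 change), with adjusted p = 2.41e-22. RPL13A went from 4194 ± 97.0 to 147 ± 0.737 and RPL39 from 4374 ± 167 to 135 ± 8.11. Among ribosome biogenesis genes, 41 of 56 fell and 8 rose (42 and 8 adjusted over the list alone). Their median was -1.32 (log2 change), with adjusted p = 7.20e-07. GAR1, part of an RNA-modifying complex, went from 2132 ± 41.1 to 179 ± 41.0. For subunits of RNA polymerases I and III, 14 of 19 fell and 1 rose. Their median was -1.53 (log2 change), with adjusted p = 8.44e-05. The largest subunit RPA190 went from 3219 ± 139 to 413 ± 23.2. In amino acid biosynthesis, 33 of 40 fell and 2 rose (34 and 2 adjusted over the list alone). Their median was -1.91 (log2 change), with adjusted p = 2.22e-10. HIS1, the first enzyme of histidine synthesis, fell (4203 ± 126 to 109 ± 19.4), while ARG3 rose (33.9 ± 5.62 to 649.6 ± 3.08). Of ergosterol genes, 18 of 23 fell and 3 rose. Their median was -1.21 (log2 change), with adjusted p = 2.03e-06. ERG4 went from 3686 ± 152 to 125 ± 21.9. Among cell wall genes, 17 of 26 fell and 5 rose (17 and 6 adjusted over the list alone). Their median was -1.81 (log2 change, -1.78 with values under background set to it), with adjusted p = 2.34e-04. The glucanase SCW10 is an example (2661 ± 52.8 to 187 ± 18.0). In the cell cycle list, 12 of 24 fell and 1 rose (11 and 1 adjusted over the list alone). Their median was -0.69 (log2 change), with adjusted p = 0.0199, but adjusted p = 0.0906 with an estimated correlation, the call kept in 8 of 9 alternatives. The G1 cyclin CLN3 is an example (-2.11 ± 0.11). For mitochondrial ribosomal proteins, 34 of 56 fell and 7 rose. Their median was -0.59 (log2 change), with adjusted p = 0.00152, but adjusted p = 0.205 with an estimated correlation, the call kept in 8 of 9 alternatives. Adding 50 before log2, which shrinks changes of dim genes, put the 18 h medians of fatty acid oxidation, autophagy, nitrogen-repressed and RNA polymerase genes at 4.31, 0.81, 0.57 and -0.90.

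The other lists were not called. In trehalose and glycogen metabolism 9 of 16 rose and 5 fell, among chaperones 11 of 24 and 7, among hydrophilins and other dehydration-induced genes 5 of 8 and 1, and in oxidative stress defence 14 of 22 and 6. In the tricarboxylic acid cycle 10 of 15 rose and 2 fell, in glycolysis and fermentation 6 of 16 and 4, in the proteasome 8 of 31 and 14, and among hexose transporters 2 of 7 and 4. In sulfur amino acid synthesis 7 of 18 rose and 8 fell, in the unfolded protein response 3 of 15 and 8, in the DNA damage response 3 of 10 and 2, and among core histones, of which 2 were measured, 0 and 2. Of lists for other cell states, meiosis and sporulation had 10 of 20 rise and 0 fall (median log2 change 1.2, or 0.17 with values under background set to it), and haploid and mating genes 6 of 16 and 1. Of 7 common reference genes 1 rose and 2 fell. The tested probe set of ACT1, the actin gene, rose by 1.29 ± 0.09, but the chip's control probe sets for ACT1 went from 5709.7 ± 411 to 2921 ± 140.4 (5'), 4738 ± 158 to 2441 ± 87.0 (middle) and 4591 ± 182 to 4455 ± 48.4 (3'), so no direction is given for ACT1. Of the 3 genes given as deleted in the strain, HIS3 and LEU2 read above background in the control, and what their probe sets detect was not tested. URA3 was at background at all time points, the HIS3 signal went from 951 ± 43.1 to 127 ± 9.60, and that of LEU2 from 69.5 ± 6.99 to 37.4 ± 6.14, a call lost without control replicate 2 or 18 h replicate 1 (-0.76 without the latter) and with scan day as a block.

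In all, 5894 of 9275 probe sets changed, 3358 higher and 2536 lower (57.0% higher), with a median log2 change of 0.11 over all probe sets. Beyond those named, large rises were those of SDH9 (at least 100-fold), SHH3 (at least 134-fold), PDH1 (at least 113-fold) and CIT3 (at least 122-fold), both of propionate breakdown, PRR2 (at least 32.4-fold), YIG1 (at least 63.4-fold), GIP1 (at least 13.3-fold), the Hsp70 chaperone SSA3 (29.5 ± 1.72 to 5246 ± 548) and the succinate carrier SFC1 (27.5 ± 3.16 to 4543 ± 143). Large falls were those of RPS26B (log2 -6.26 ± 0.54), HEM13, of heme synthesis (signal 708 ± 74.8 to 20.0 ± 23.6), the acid phosphatase PHO3 (-5.78 ± 0.33), IMD4 (-5.62 ± 0.25), FSH1 (-5.47 ± 0.24), transketolase TKL1 (-5.29 ± 0.13), and those to background of RCK1 (at least 6.51-fold), AAC3 (at least 5.06-fold), KEL3 (at least 4.67-fold), HOR7 (at least 37.8-fold) and FKS1, a glucan synthase (at least 26.2-fold). The 7 other FKS1 probe sets fell too, the brightest changing by -2.10, and the HOR7 call is lost within scan day 1, which holds 1 array of 18 h. The 3' to 5' ratio of the ACT1 control probe sets, a measure of RNA quality, was 0.92 higher at 18 h (log2, exact permutation p = 0.1, two-sided, the smallest possible), that of SRB4 0.97 higher and that of SPT15 0.15 higher (exact permutation p = 0.4). Scan day as a block rests on the 1 array of 18 h scanned on day 1, as does a fit within day 1. Both gave medians of 5.25 for fatty acid oxidation, 5.27 for the glyoxylate cycle and -2.58 for ribosomal proteins. They take the spread from the other groups and assume that array varies like them. Scaling on the spike-in probe sets (the 9 chip controls named BioB, BioC, BioDn and CreX) shifts every log2 change by -0.29. It gave 2290 higher and 2878 lower (44.3% higher), and the called lists kept the direction of their medians. Whether each array received the same amount of labelled target is not known here, so spike-in scaling does not give RNA per cell.

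**Figure D2:**
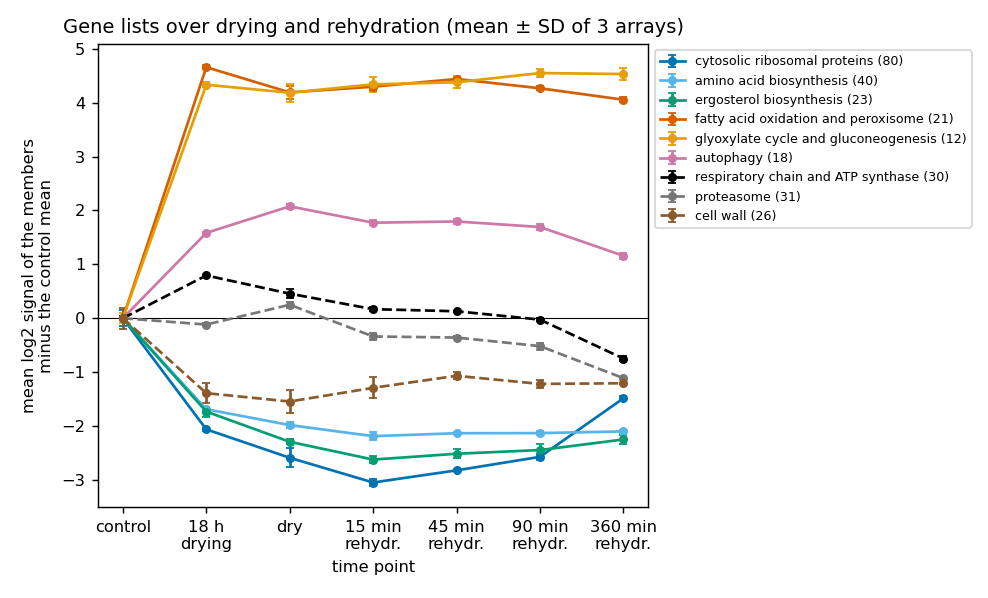
Mean log2 signal of 9 gene lists at each time point minus that in the control, as mean ± SD of 3 arrays. Ribosomal protein genes lie below the control at all later points, and fatty acid oxidation and glyoxylate cycle genes above it.

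The comparison of the dry state with 18 h asks what changed between partial and full dryness. Hexose transporter, tricarboxylic acid cycle, respiratory and fatty acid oxidation genes fell. Among hexose transporters, 6 of 7 fell and 0 rose. Their median was -0.94 (log2 change), with adjusted p = 8.14e-05. HXT2 went from 1832 ± 70.0 to 713 ± 110.2. Of tricarboxylic acid cycle genes, 8 of 15 fell and 0 rose (9 and 0 adjusted over the list alone). Their median was -0.46 (log2 change), with adjusted p = 2.44e-05. The succinyl-CoA ligase subunit LSC2 is an example (2414 ± 83.7 to 796 ± 21.6). In the respiratory chain, 15 of 30 fell and 2 rose (16 and 2 adjusted over the list alone). Their median was -0.37 (log2 change), with adjusted p = 5.04e-04. COX4 is an example (-1.04 ± 0.09). Among fatty acid oxidation genes, 12 of 21 fell and 0 rose. Their median was -0.38 (log2 change), with adjusted p = 2.70e-04. The thioesterase TES1 is an example (4919 ± 359 to 2127 ± 135). For proteasome subunits, 17 of 31 rose and 1 fell (20 and 1 adjusted over the list alone). Their median was 0.41 (log2 change), with adjusted p = 0.00176, but adjusted p = 0.0819 with an estimated correlation, the call kept in 8 of 9 alternatives. PUP3 went from 1701 ± 240.3 to 3258 ± 204. Of autophagy genes, 8 of 18 rose and 1 fell (9 and 1 adjusted over the list alone). Their median was 0.47 (log2 change), with adjusted p = 0.0415, but adjusted p = 0.0785 with an estimated correlation, the call kept in 6 of 9 alternatives. ATG19 went from 934 ± 71.2 to 2110.0 ± 226.

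Among ribosomal proteins, 40 of 80 fell and 6 rose (44 and 6 adjusted over the list alone). Their median was -0.52 (log2 change, -0.51 with values under background set to it), with adjusted p = 7.60e-09, but adjusted p = 0.0787 with an estimated correlation, the call kept in 8 of 9 alternatives. RPL3 went from 903 ± 67.5 to 324 ± 57.4. Of cell wall genes, 15 of 26 fell and 4 rose (16 and 5 adjusted over the list alone). Their median was -0.73 (log2 change, -0.65 with values under background set to it), with adjusted p = 0.00257. The chitin synthase CHS1 rose (1.69 ± 0.11) and the glucanase EXG1 fell (-1.57 ± 0.15). In ergosterol synthesis, 13 of 23 fell and 4 rose. Their median was -0.68 (log2 change, -0.57 with values under background set to it), with adjusted p = 1.99e-04, but adjusted p = 0.0817 with an estimated correlation, the call kept in 8 of 9 alternatives. ERG6 went from 1600.3 ± 251 to 143 ± 4.4. For amino acid biosynthesis, 15 of 40 fell and 5 rose. Their median was -0.33 (log2 change), with adjusted p = 0.0335, but adjusted p = 0.0791 with an estimated correlation, the call kept in 7 of 9 alternatives. THR1 is an example (-2.20 ± 0.14). In trehalose and glycogen metabolism, 6 of 16 fell and 1 rose (8 and 1 adjusted over the list alone). Their median was -0.28 (log2 change), with adjusted p = 0.0268, but adjusted p = 0.160 with an estimated correlation, the call kept in 6 of 9 alternatives. Glycogen phosphorylase GPH1 went from 2082 ± 254 to 549.7 ± 4.91. ADH2, which oxidizes ethanol, went from 92.2 ± 115 to 5795 ± 2207, the mannoprotein TIP1 from 320.5 ± 200.2 to 4776 ± 676 and SRL4 from 29.9 ± 5.05 to 459 ± 31.4. SNF7, of endosomal sorting, was at background at 18 h and at least 3.14-fold higher dry, although the brightest of 2 other probe sets rose by 0.94, and IRC10 was at least 2.09-fold higher. YCH1 fell at least 8.16-fold, to background, and the arginine permease ALP1 (-4.15 ± 0.20), NCA3 (-3.40 ± 0.21) and REE1 (-3.23 ± 0.17) fell too. CTT1 (-1.01 ± 0.20), STF2 (-0.57 ± 0.12) and FBP1 (-1.19 ± 0.13) fell, and SIP18 (-0.02 ± 0.19), GRE1 (-0.04 ± 0.22), HSP26 (-0.04 ± 0.09) and HSP104 (0.20 ± 0.13) did not pass. In all, 3633 of 9275 probe sets changed, 2053 higher and 1580 lower (56.5% higher), with a median log2 change of 0.06 over all probe sets. The ACT1 3' to 5' ratio was 0.44 higher dry and that of SPT15 lower by 0.54 (log2 -0.54, exact permutation p = 0.1 for each), and that of SRB4 changed by -0.07 (exact permutation p = 0.7). Scan day as a block left 3385 changes, and leaving out the 18 h array of another day (other groups kept for the spread) 3288. Both gave medians of -0.52 for ribosomal proteins, 0.38 for the proteasome and -0.55 for the cell wall. Median centring gave 1515 higher and 2136 lower (41.5% higher).

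Against the control, the dry state adds up both steps. Fatty acid oxidation and glyoxylate cycle genes were higher, and ribosomal protein, amino acid and ergosterol genes lower. Of fatty acid oxidation genes, 20 of 21 rose and 1 fell. Their median was 4.52 (log2 change), with adjusted p = 2.07e-09. Of glyoxylate cycle genes, 10 of 12 rose and 0 fell. Their median was 4.77 (log2 change), with adjusted p = 1.96e-05. CTA1 went from 52.1 ± 6.69 to 5241 ± 429.7. Among autophagy genes, 17 of 18 rose and 1 fell. Their median was 2.14 (log2 change, 2.04 with values under background set to it), with adjusted p = 1.70e-04. ATG3 went from 181 ± 17.5 to 1436 ± 32.6. For general stress genes, 17 of 24 rose and 4 fell. Their median was 1.64 (log2 change), with adjusted p = 0.00370, but adjusted p = 0.136 with an estimated correlation, the call kept in 8 of 9 alternatives. The aldehyde dehydrogenase ALD3 is an example (116 ± 15.9 to 2113 ± 329). For nitrogen-repressed genes, 13 of 19 rose and 2 fell. Their median was 1.39 (log2 change, 1.00 with values under background set to it), with adjusted p = 0.0135, but adjusted p = 0.0956 with an estimated correlation, the call kept in 8 of 9 alternatives. The ammonium permease MEP2 is an example (79.1 ± 3.63 to 1624 ± 161). Of ribosomal protein genes, 74 of 80 fell and 5 rose (74 and 6 adjusted over the list alone). Their median was -3.07 (log2 change), with adjusted p = 1.41e-24. RPP1B went from 4925 ± 132 to 505 ± 59.4. With quantile normalization that median was -3.67. Among ribosome biogenesis genes, 33 of 56 fell and 7 rose. Their median was -1.19 (log2 change), with adjusted p = 3.93e-06. NOP1, which methylates ribosomal RNA, went from 2846 ± 13.7 to 116 ± 15.7. Among polymerase I and III subunits, 15 of 19 fell and 2 rose. Their median was -0.87 (log2 change), with adjusted p = 4.55e-04. Of amino acid genes, 34 of 40 fell and 2 rose. Their median was -2.17 (log2 change), with adjusted p = 2.74e-11. Of ergosterol genes, 19 of 23 fell and 2 rose. Their median was -1.59 (log2 change), with adjusted p = 8.25e-08. Of cell wall genes, 18 of 26 fell and 4 rose. Their median was -1.29 (log2 change), with adjusted p = 1.30e-04. THR1 went from 3849 ± 419 to 188 ± 5.25 and ERG3 from 4288 ± 76.3 to 239 ± 30.8.

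Among hexose transporters, 6 of 7 fell and 1 rose. Their median was -2.09 (log2 change), with adjusted p = 0.00381, but adjusted p = 0.0508 with an estimated correlation, the call kept in 8 of 9 alternatives. HXT3 went from 5015 ± 377 to 115 ± 6.09 and HXT1 from 2998 ± 299 to 156 ± 12.8, while HXT5 rose (106 ± 5.48 to 4503 ± 379.6). Of cell cycle genes, 16 of 24 fell and 4 rose (16 and 5 adjusted over the list alone). Their median was -0.91 (log2 change, -0.85 with values under background set to it), with adjusted p = 0.00487, but adjusted p = 0.0501 with an estimated correlation, the call kept in 8 of 9 alternatives. Of mitochondrial ribosomal proteins, 22 of 56 fell and 7 rose (21 and 7 adjusted over the list alone). Their median was -0.26 (log2 change), with adjusted p = 0.0419, but adjusted p = 0.415 with an estimated correlation, the call kept in 6 of 9 alternatives. SIP18 was at least 143-fold, PRR2 at least 46.1-fold, SDH9 at least 89.4-fold, SHH3 at least 131-fold and CRC1 at least 147-fold higher, and HOR7 at least 37.8-fold, HEM13 at least 23.8-fold, FKS1 at least 26.2-fold, PAN5 at least 25.1-fold and RPS26B at least 65.1-fold lower. The brightest other FKS1 probe set changed by -3.00, and the HOR7 call is lost with scan day as a block. HSP26 rose by 3.78 ± 0.09, GRE1 by 7.29 ± 0.22, HSP104 by 0.93 ± 0.13 and TPS1 by 0.37 ± 0.09, the last not with scan day as a block, and HSP12 (-0.31 ± 0.24) and TPS2 (-0.24 ± 0.18) did not pass. In all, 6239 of 9275 probe sets changed, 3717 higher and 2522 lower (59.6% higher), with a median log2 change of 0.24 over all probe sets. The ACT1 3' to 5' ratio was 1.36 and that of SRB4 0.90 higher dry, and that of SPT15 lower by 0.39 (log2 -0.39, exact permutation p = 0.1 for each). Both groups share no scan day, and day as a block left 4599 changes. Median centring gave 2957 higher and 3194 lower (48.1% higher) and spike-in scaling, a shift of -0.31, 2721 higher and 2869 lower (48.7% higher), with the medians of the called lists keeping their direction.

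**Figure D3:**
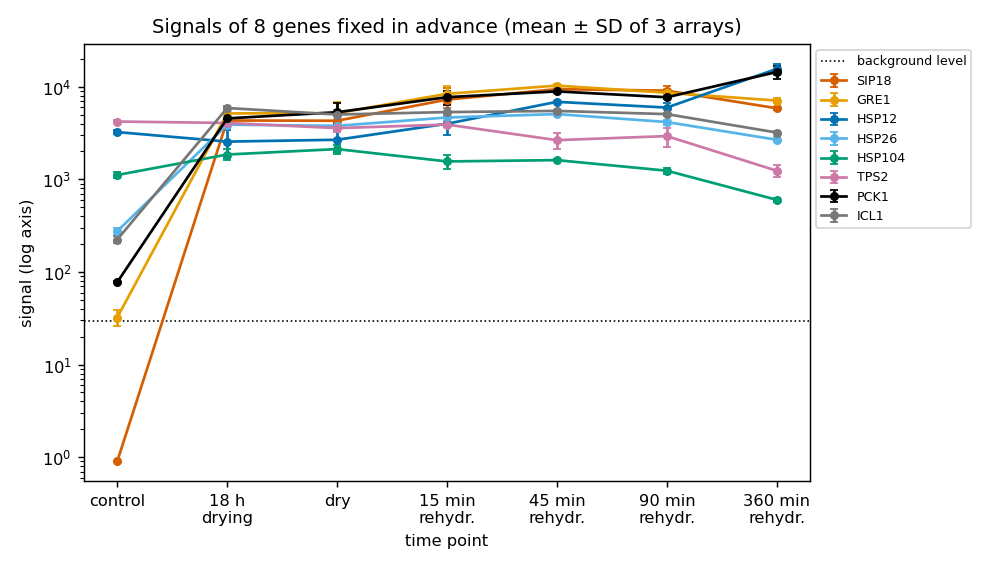
Signals of SIP18, GRE1, HSP12, HSP26, HSP104, TPS2, PCK1 and ICL1 at the 7 time points, on a log axis, as mean ± SD of 3 arrays, with the background level of 29.6 dotted. SIP18 lies below background in the control and at 4322 at 18 h, and HSP12 reaches 15592 at 360 min.

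Rehydration for 15 min, against the dry state, asks for the first response to water. Proteasome genes fell, and hexose transporter and cell wall genes rose. For the proteasome, 20 of 31 fell and 0 rose (21 and 0 adjusted over the list alone). Their median was -0.54 (log2 change), with adjusted p = 4.46e-05. PUP3 went from 3258 ± 204 to 1184 ± 144 and RPN12 from 972 ± 80.0 to 407 ± 16. Among hexose transporters, 5 of 7 rose and 0 fell. Their median was 0.41 (log2 change), with adjusted p = 1.75e-04. HXT2 went from 713 ± 110.2 to 1565 ± 165. Among cell wall genes, 13 of 26 rose and 0 fell (15 and 0 adjusted over the list alone). Their median was 0.36 (log2 change, 0.35 with values under background set to it), with adjusted p = 1.13e-05. SCW4 went from 2846 ± 259 to 5797 ± 561. Of ribosomal protein genes, 38 of 80 fell and 8 rose (38 and 9 adjusted over the list alone). Their median was -0.46 (log2 change), with adjusted p = 0.0114, but adjusted p = 0.451 with an estimated correlation, the call kept in 7 of 9 alternatives. RPL37B went from 1272 ± 158 to 326 ± 16.4. Of ribosome biogenesis genes, 22 of 56 fell and 1 rose. Their median was -0.40 (log2 change, -0.37 with values under background set to it), with adjusted p = 0.0376, but adjusted p = 0.151 with an estimated correlation, the call kept in 5 of 9 alternatives. The small nucleolar RNAs SNR66 (132 ± 10.9 to 744 ± 151) and SNR61 (692 ± 252 to 3719 ± 867) and the mitochondrially encoded ATP6 (263 ± 131 to 1161 ± 416) rose, as did EFM6 (at least 1.07-fold) and, at background in both groups, SNR65. Falls to background were those of NAT5 (at least 5.43-fold), CPD1 (at least 7.99-fold), AIM20 (at least 1.41-fold), MRPS5 (at least 1.29-fold) and YSF3 (at least 1.03-fold).

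SIP18 went from 4297 ± 736 to 7265 ± 2351 and POX1 from 2269.9 ± 181 to 3717 ± 575, and TPS1 rose by 0.43 ± 0.09. GRE1 rose by 0.73 ± 0.22, or by 0.43 without dry replicate 3, and its call is lost without that array or 15 min replicate 3. Calls that also depend on single arrays are those of HSP26 (0.30 ± 0.09, dry 3, 15 min 3), PCK1 (0.56 ± 0.17, dry 3, 15 min 1, 3), HXT5 (0.41 ± 0.14, dry 2, 3, 15 min 1, 3), HSP104 (-0.45 ± 0.13, dry 1, 15 min 2), CTT1 (-0.66 ± 0.20, dry 2, 15 min 1) and STF2 (-0.36 ± 0.12, dry 1, 3, 15 min 1, 3), where the numbers are the replicates whose removal ends the call. With 1 array left out, the changes nearest 0 for these 6 genes were 0.24, 0.35, 0.30, -0.31, -0.50 and -0.27. In all, 3737 of 9275 probe sets changed, 1186 higher and 2551 lower (31.7% higher), with a median log2 change of -0.18 over all probe sets, both groups being of scan day 2. The 3' to 5' ratios of ACT1, SPT15 and SRB4 were 0.68, 1.12 and 0.38 higher at 15 min (log2, exact permutation p = 0.1 for each). The split depends on scaling: quantile normalization gave 1592 higher and 1531 lower (51.0% higher), median centring 2573 higher and 1085 lower (70.3% higher), rescaling on the dimmer probe sets 1551 higher and 1931 lower (44.5% higher), and spike-in scaling, a shift of -0.73, 75 higher and 5849 lower (1.27% higher). With that shift the medians of hexose transporters and cell wall genes are below 0, and quantile normalization turns HSP26 to -0.07 and HXT5 to -0.07 while median centring turns STF2 to 0.03.

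**Figure D4:**
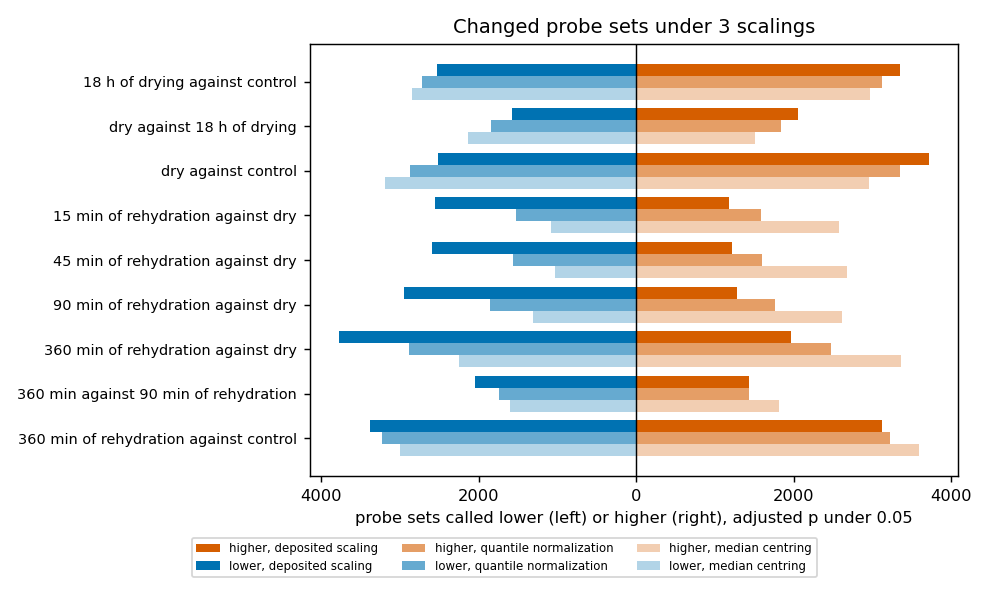
Probe sets called higher and lower in each of the 9 comparisons with the deposited scaling, with quantile normalization and with median centring. At 15 min against dry the share higher is 31.7%, 51.0% and 70.3%.

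After 45 min the same 3 lists had moved in the direction seen at 15 min. Of proteasome genes, 22 of 31 fell and 0 rose. Their median was -0.63 (log2 change), with adjusted p = 4.98e-06. PRE4 went from 1578 ± 86.1 to 778 ± 55.9. Among hexose transporters, 5 of 7 rose and 0 fell (7 and 0 adjusted over the list alone). Their median was 0.62 (log2 change), with adjusted p = 2.53e-05. Among cell wall genes, 15 of 26 rose and 0 fell (16 and 0 adjusted over the list alone). Their median was 0.53 (log2 change, 0.45 with values under background set to it), with adjusted p = 1.47e-06. CIS3 went from 281 ± 25.3 to 654 ± 19.8. Of fatty acid oxidation genes, 10 of 21 rose and 5 fell (11 and 5 adjusted over the list alone). Their median was 0.28 (log2 change), with adjusted p = 0.00784, but adjusted p = 0.0787 with an estimated correlation, the call kept in 7 of 9 alternatives. CTA1 rose by 0.69 ± 0.10 and DCI1 fell (-1.11 ± 0.18). HSP12, a membrane-protecting stress protein, went from 2678 ± 707 to 6875 ± 223, SIP18 from 4297 ± 736 to 9424 ± 822 and GRE1 from 5187 ± 1653 to 10290.4 ± 298. PCK1 rose by 0.78 ± 0.17, POX1 by 0.70 ± 0.12, TPS1 by 0.43 ± 0.09 and HSP26 by 0.42 ± 0.09, while CTT1 fell (-0.89 ± 0.20). The call of MLS1 (0.55 ± 0.19) is lost without dry replicate 1 or 3 or 45 min replicate 1 or 2, of HSP104 (-0.39 ± 0.13) without dry 1 or 2 or 45 min 3, and of STF2 (-0.32 ± 0.12) without any one of the 6 arrays but dry 2. Their changes nearest 0 with 1 array left out were 0.37, -0.31 and -0.23.

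The stress gene HOR7, at background dry, rose at least 134-fold. DDR2, another stress gene, rose by 4.64 ± 1.60, but by 1.5 without dry replicate 3, and the call is lost without any one 45 min array. SNR66 rose by 2.36 ± 0.17, and BRN1 and BI2 rose at background in both groups, BI2 not without 45 min replicate 1. MRPS5 (at least 1.29-fold), RIF2 (at least 1.10-fold), NKP2 (at least 1.30-fold) and ARP1 (at least 1.66-fold) fell to background, and PET112 went from 109.8 ± 34.0 to 20.9 ± 19.4, a fall whose size depends on 45 min replicate 1. In all, 3816 of 9275 probe sets changed, 1220 higher and 2596 lower (32.0% higher), with a median log2 change of -0.18 over all probe sets, both groups again of scan day 2. The ACT1, SPT15 and SRB4 3' to 5' ratios were 0.85, 1.08 and 0.59 higher at 45 min (log2, exact permutation p = 0.1 for each). Quantile normalization gave 1604 higher and 1568 lower (50.6% higher), median centring 2673 higher and 1035 lower (72.1% higher), rescaling on the dimmer probe sets 1651 higher and 1912 lower (46.3% higher) and spike-in scaling, a shift of -0.72, 93 higher and 5821 lower (1.57% higher). With that shift the hexose transporter, cell wall and fatty acid oxidation medians are below 0, and quantile normalization puts that of fatty acid oxidation at -0.06, CTA1 at -0.07 and HSP26 at -0.01, while median centring puts HSP104 at 0.02 and STF2 at 0.09.

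At 90 min against dry, proteasome genes were lower and hexose transporter and cell wall genes higher. In the proteasome, 27 of 31 fell and 0 rose (28 and 0 adjusted over the list alone). Their median was -0.69 (log2 change), with adjusted p = 4.23e-07. RPN9 went from 860.0 ± 98.2 to 362 ± 23.2. Of hexose transporters, 6 of 7 rose and 0 fell (7 and 0 adjusted over the list alone). Their median was 0.71 (log2 change), with adjusted p = 3.08e-05. Of cell wall genes, 12 of 26 rose and 3 fell. Their median was 0.44 (log2 change), with adjusted p = 5.26e-04. GAS1 rose (1.16 ± 0.16) and PIR3 fell (-1.30 ± 0.14). For nuclear respiratory genes, 18 of 30 fell and 4 rose. Their median was -0.55 (log2 change), with adjusted p = 0.0199, but adjusted p = 0.0854 with an estimated correlation, the call kept in 5 of 8 alternatives. COX6 went from 2455 ± 166 to 969.8 ± 135. Of glyoxylate cycle genes, 5 of 12 rose and 1 fell. Their median was 0.35 (log2 change, 0.24 with values under background set to it), with adjusted p = 0.0498, but adjusted p = 0.278 with an estimated correlation, the call kept in 3 of 8 alternatives. The malate dehydrogenase MDH2 is an example (4389.9 ± 1093 to 6769 ± 344). HSP12 went from 2678 ± 707 to 5962 ± 702 and SIP18 from 4297 ± 736 to 9080.1 ± 1113, POX1 rose by 0.97 ± 0.12, and HSP104 (-0.77 ± 0.13) and STF2 (-0.55 ± 0.12) fell. GRE1 rose by 0.79 ± 0.22, or by 0.49 without dry replicate 3. The calls of PCK1 (0.57 ± 0.17), MLS1 (0.60 ± 0.19) and CTT1 (-0.60 ± 0.20) are lost without dry replicate 3. They are also lost without 90 min replicate 1 for MLS1 and CTT1, and without dry replicate 2 or 90 min replicate 3 for CTT1. The changes nearest 0 with 1 array left out were 0.36, 0.43 and -0.45.

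HOR7 was at least 6.56-fold higher from background, but its call is lost without any dry array or without 90 min replicate 1 or 3. DDR2 rose by 4.62 ± 1.60, or 1.48 without dry replicate 3, a call lost without any one 90 min array. The mitochondrially encoded ATP6 (263 ± 131 to 2114 ± 479), SCEI (23.0 ± 10.3 to 206 ± 166) and BI2 (at least 1.23-fold) rose. CDC6, a replication factor (at least 2.64-fold), APS3 (at least 2.06-fold), CPD1 (at least 7.99-fold), MRPS5 (at least 1.29-fold) and NAT5 (at least 5.43-fold) fell to background. In all, 4238 of 9275 probe sets changed, 1286 higher and 2952 lower (30.3% higher), with a median log2 change of -0.23 over all probe sets. The ACT1, SPT15 and SRB4 3' to 5' ratios were 1.38, 1.39 and 0.74 higher at 90 min (log2, exact permutation p = 0.1 for each). Scan day and time cannot be told apart here, and without 90 min replicate 2, scanned alone on day 4, 4029 probe sets changed. Quantile normalization gave 1762 higher and 1860 lower (48.6% higher), median centring 2613 higher and 1311 lower (66.6% higher), rescaling on the dimmer probe sets 1741 higher and 2147 lower (44.8% higher) and spike-in scaling, a shift of -1.05, 91 higher and 7051 lower (1.27% higher), the last putting the hexose transporter, cell wall and glyoxylate medians below 0. Quantile normalization puts the glyoxylate median at -0.16.

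At 360 min against dry, ribosomal protein genes rose, and proteasome and nuclear respiratory genes fell. Of cytosolic ribosomal protein genes, 57 of 80 rose and 3 fell (57 and 4 adjusted over the list alone). Their median was 1.24 (log2 change), with adjusted p = 4.29e-15. RPS2 went from 1607 ± 98 to 7748 ± 268 and RPS12 from 1142 ± 177 to 3858 ± 81.0, and RPS26B, at background dry, was at least 14.9-fold higher. Of proteasome genes, 31 of 31 fell and 0 rose. Their median was -1.31 (log2 change), with adjusted p = 7.60e-09. RPN12 went from 972 ± 80.0 to 122 ± 19.3. For the respiratory chain, 23 of 30 fell and 2 rose. Their median was -1.23 (log2 change), with adjusted p = 7.51e-05. The iron-sulfur subunit RIP1 went from 3621 ± 118 to 441 ± 16.3 and COX5A from 2265 ± 86.0 to 368 ± 37.4. Among mitochondrial ribosomal proteins, 40 of 56 fell and 0 rose. Their median was -0.84 (log2 change, -0.74 with values under background set to it), with adjusted p = 5.59e-04, but adjusted p = 0.170 with an estimated correlation, the call kept in 7 of 8 alternatives. In glycolysis and fermentation, 10 of 16 rose and 4 fell (11 and 4 adjusted over the list alone). Their median was 0.92 (log2 change), with adjusted p = 0.0191, but adjusted p = 0.196 with an estimated correlation, the call kept in 6 of 8 alternatives. TDH1 went from 1941 ± 165 to 7234 ± 448 and pyruvate decarboxylase PDC1 from 4019 ± 147 to 10076 ± 264. Of hexose transporters, 7 of 7 rose and 0 fell. Their median was 0.65 (log2 change), with adjusted p = 0.00143. Of cell wall genes, 12 of 26 rose and 7 fell. Their median was 0.40 (log2 change), with adjusted p = 0.0476, but adjusted p = 0.155 with an estimated correlation, the call kept in 3 of 8 alternatives. SCW4 rose (2846 ± 259 to 10076 ± 823) and YPS1 fell (-1.64 ± 0.10). Among chaperones, 14 of 24 fell and 3 rose. Their median was -0.43 (log2 change), with adjusted p = 0.0433, but adjusted p = 0.116 with an estimated correlation, the call kept in 5 of 8 alternatives. HSP78 is an example (1339.7 ± 69.9 to 377 ± 20.7). Under quantile normalization the glycolysis median is -0.23, and under median centring the chaperone median is 0.09.

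HSP12 went from 2678 ± 707 to 15592 ± 2084, PCK1 from 5307 ± 1382 to 14426 ± 2222 and MLS1 from 4199 ± 1042 to 8269.6 ± 337. POX1 rose by 1.15 ± 0.12. The tested ACT1 probe set changed by 0.58 ± 0.09, its control probe sets going from 1375 ± 104 to 1029 ± 43.7 (5'), 1176 ± 70.2 to 1221 ± 99.4 (middle) and 2837 ± 49.3 to 5154 ± 376 (3'). HSP104 (-1.82 ± 0.13), TPS2 (-1.54 ± 0.18), STF2 (-1.33 ± 0.12), CTT1 (-0.79 ± 0.20), ICL1 (-0.64 ± 0.10) and HSP26 (-0.50 ± 0.09, 0.02 with median centring) fell, and GRE1 (0.51 ± 0.22) and TPS1 (0.00 ± 0.09) did not pass. SIP18 was higher by 0.46 ± 0.19, a call lost without dry replicate 2 or 3 (0.32 without the latter) or any one 360 min array, and -0.31 with quantile normalization. HOR7 was at least 352-fold and the G1 cyclin CLN2 at least 3.59-fold higher. DDR2 rose by 3.94 ± 1.60, or 0.80 without dry replicate 3, a call lost without any one 360 min array. SNR61 (692 ± 252 to 11595 ± 906) and SNR66 (132 ± 10.9 to 1879 ± 166) rose, with mitochondrially encoded SCEI (23.0 ± 10.3 to 295 ± 39.1), ATP6 (log2 3.58 ± 0.40), BI2 (at least 1.55-fold), COB (3.48 ± 0.17 and 3.36 ± 0.23 on 2 probe sets) and COX1 (3.45 ± 0.09, the brightest of its other probe sets 1.65). Falls were those of the squalene epoxidase ERG1 (380.5 ± 48.7 to 24.5 ± 13.6), CPD1 (239.6 ± 43.2 to 18.9 ± 13.4), ECM13 (log2 -4.01 ± 0.13) and BLI1 (-3.80 ± 0.41). Falls to background were those of CDC6 (at least 2.64-fold), APS3 (at least 2.06-fold), MCH2 (at least 4.24-fold), FMP25 (at least 9.93-fold), CDA1 (at least 1.84-fold), SNT309 (at least 7.08-fold), MSH5 (at least 3.77-fold) and SNF7 (at least 3.14-fold, its brightest other probe set changing by -0.98).

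In all, 5743 of 9275 probe sets changed, 1970 higher and 3773 lower (34.3% higher), with a median log2 change of -0.29 over all probe sets. The ACT1, SPT15 and SRB4 3' to 5' ratios were 1.27, 1.51 and 0.42 higher at 360 min (log2, exact permutation p = 0.1 for each), and scan day cannot be told apart from time here. Quantile normalization gave 2482 higher and 2892 lower (46.2% higher), median centring 3370 higher and 2251 lower (60.0% higher) and spike-in scaling, a shift of -2.01, 66 higher and 7993 lower (0.819% higher). With that shift the medians of ribosomal protein, glycolysis, hexose transporter and cell wall genes are all below 0, as are the changes of SIP18, PCK1, MLS1 and POX1.

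**Figure D5:**
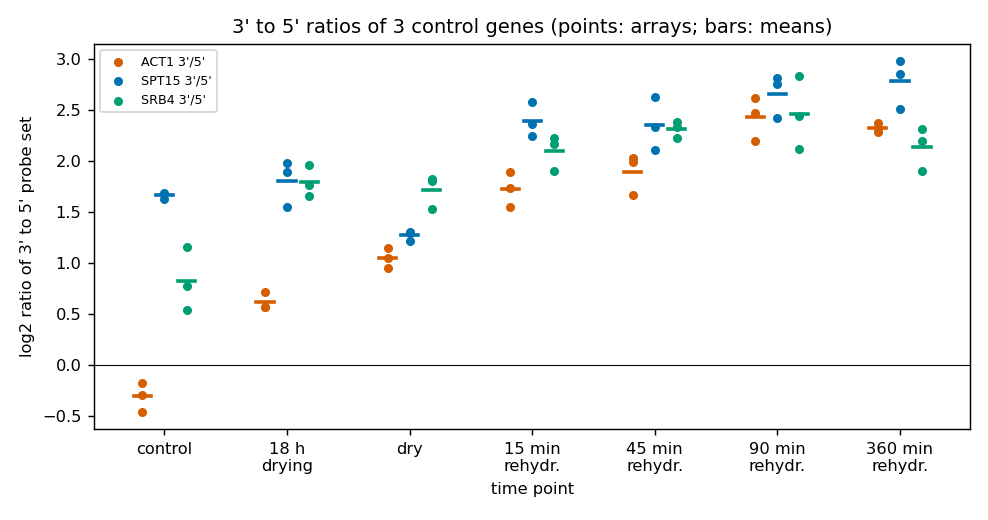
Log2 ratio of 3' to 5' control probe set signals for ACT1, SPT15 and SRB4, one point per array with the mean of each time point. The ACT1 mean is -0.31 in the control, 1.05 dry and 2.32 at 360 min.

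From 90 to 360 min, ribosomal protein genes rose and respiratory, proteasome and autophagy genes fell. Of ribosomal protein genes, 68 of 80 rose and 0 fell (69 and 0 adjusted over the list alone). Their median was 1.10 (log2 change), with adjusted p = 1.42e-27. RPP1B went from 487 ± 27.1 to 1288 ± 24.8. In the respiratory chain, 19 of 30 fell and 0 rose (20 and 0 adjusted over the list alone). Their median was -0.58 (log2 change), with adjusted p = 2.61e-07. COX5A went from 1547 ± 76.4 to 368 ± 37.4. In the tricarboxylic acid cycle, 8 of 15 fell and 1 rose. Their median was -0.35 (log2 change), with adjusted p = 0.00764. The succinate dehydrogenase subunit SDH2 went from 4793 ± 459.6 to 1634 ± 27.7. Of proteasome genes, 23 of 31 fell and 0 rose (24 and 0 adjusted over the list alone). Their median was -0.57 (log2 change), with adjusted p = 7.50e-08. RPN1 went from 954 ± 73.0 to 331 ± 28.2. Of autophagy genes, 9 of 18 fell and 0 rose. Their median was -0.64 (log2 change), with adjusted p = 0.00531. ATG1 went from 1208 ± 111 to 455 ± 47.2. Among general stress genes, 14 of 24 fell and 5 rose (15 and 5 adjusted over the list alone). Their median was -0.62 (log2 change), with adjusted p = 0.00243, but adjusted p = 0.118 with an estimated correlation, the call kept in 8 of 9 alternatives. XBP1 went from 4743 ± 263 to 988 ± 129. Among chaperones, 13 of 24 fell and 1 rose (14 and 1 adjusted over the list alone). Their median was -0.40 (log2 change), with adjusted p = 0.00287. HSP30 went from 723 ± 109 to 239 ± 8.60. For oxidative stress defence, 8 of 22 fell and 0 rose. Their median was -0.20 (log2 change), with adjusted p = 0.0427, but adjusted p = 0.0767 with an estimated correlation, the call kept in 5 of 9 alternatives. The glutaredoxin GRX2 is an example (-1.44 ± 0.12). In glycolysis, 8 of 16 rose and 3 fell (9 and 3 adjusted over the list alone). Their median was 0.61 (log2 change), with adjusted p = 0.0105, but adjusted p = 0.163 with an estimated correlation, the call kept in 7 of 9 alternatives. The hexokinase HXK2 went from 213 ± 3.67 to 419.5 ± 5.55. Of ergosterol genes, 10 of 23 rose and 4 fell (11 and 4 adjusted over the list alone). Their median was 0.31 (log2 change), with adjusted p = 0.0416, but adjusted p = 0.311 with an estimated correlation, the call kept in 7 of 9 alternatives. ERG6 rose (1.23 ± 0.11) and ERG1 fell (103 ± 10.0 to 24.5 ± 13.6). Of mitochondrial ribosomal proteins, 25 of 56 fell and 0 rose. Their median was -0.47 (log2 change, -0.46 with values under background set to it), with adjusted p = 8.61e-05, but adjusted p = 0.118 with an estimated correlation, the call kept in 8 of 9 alternatives.

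HSP12 rose by 1.39 ± 0.24 and PCK1 by 0.89 ± 0.17. HSP104 (-1.04 ± 0.13), TPS2 (-1.23 ± 0.18), STF2 (-0.78 ± 0.12), HSP26 (-0.64 ± 0.09) and ICL1 (-0.66 ± 0.10) fell, as did SIP18 (-0.63 ± 0.19), though not without 90 min replicate 1 (-0.57) or 3. HOR7 rose by 5.74 ± 2.01, or 3.46 without 90 min replicate 2, where the call is lost, as it is without any one 360 min array. CLN2 (at least 3.59-fold), the metal carrier MMT1 (at least 1.61-fold) and SEC63 (at least 1.93-fold) rose from background, and PHO3 rose by 2.97 ± 0.33. TMA16 (at least 1.51-fold), SNT309 (at least 2.81-fold), FMP25 (at least 3.07-fold) and MCH2 (at least 1.13-fold) fell to background, and UGA3 was called lower on 1 probe set, with 360 min at background and 90 min about there, while none of its 3 others passed (0.13 to 0.30). In all, 3471 of 9275 probe sets changed, 1429 higher and 2042 lower (41.2% higher), with a median log2 change of -0.02 over all probe sets. The 3' to 5' ratio of ACT1 changed by -0.10, that of SPT15 by 0.12 (exact permutation p = 0.5 for each) and that of SRB4 by -0.32 (exact permutation p = 0.3). Scan day as a block left 3166 changes, and leaving out 90 min replicate 2, of another day (other groups kept for the spread), 3130. Both gave medians of 1.11 for ribosomal proteins, -0.63 for the respiratory chain, -0.60 for the proteasome and -0.38 for autophagy. Median centring gave 1812 higher and 1598 lower (53.1% higher) and spike-in scaling, a shift of -0.96, 69 higher and 5950 lower (1.15% higher), with the ribosomal protein median still above 0 and those of glycolysis and ergosterol below it.

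The comparison of 360 min with the control cannot tell recovery from changes of medium, temperature or time. Fatty acid oxidation and glyoxylate cycle genes were higher, and ribosome biogenesis, amino acid and ergosterol genes lower. Of fatty acid oxidation genes, 19 of 21 rose and 1 fell. Their median was 4.44 (log2 change), with adjusted p = 9.98e-10. Of glyoxylate cycle genes, 10 of 12 rose and 0 fell. Their median was 4.56 (log2 change), with adjusted p = 1.93e-06. The peroxisomal citrate synthase CIT2 went from 415 ± 33.7 to 7654 ± 431. Of autophagy genes, 12 of 18 rose and 1 fell. Their median was 0.96 (log2 change), with adjusted p = 0.00867. ATG8 went from 1498 ± 37.8 to 7261 ± 535. Among general stress genes, 14 of 24 rose and 7 fell. Their median was 0.61 (log2 change), with adjusted p = 0.0399, but adjusted p = 0.275 with an estimated correlation, the call kept in 6 of 8 alternatives. MSC1 is an example (1213 ± 39.2 to 10630.5 ± 107). Among nitrogen-repressed genes, 12 of 19 rose and 4 fell. Their median was 1.10 (log2 change, 0.77 with values under background set to it), with adjusted p = 0.0241, but adjusted p = 0.121 with an estimated correlation, the call kept in 7 of 8 alternatives. The proline oxidase PUT1 is an example (334 ± 17.7 to 8520.0 ± 1509.8). Of ribosomal protein genes, 70 of 80 fell and 8 rose. Their median was -1.91 (log2 change), with adjusted p = 2.15e-10, but adjusted p = 0.0508 with an estimated correlation, the call kept in 7 of 8 alternatives. RPS0A went from 4906 ± 179 to 562 ± 72.1. Among ribosome biogenesis genes, 47 of 56 fell and 2 rose (48 and 2 adjusted over the list alone). Their median was -1.44 (log2 change, -1.41 with values under background set to it), with adjusted p = 2.21e-07. Among polymerase I and III subunits, 16 of 19 fell and 1 rose (17 and 1 adjusted over the list alone). Their median was -1.58 (log2 change), with adjusted p = 1.01e-04. Of amino acid genes, 37 of 40 fell and 3 rose. Their median was -2.45 (log2 change), with adjusted p = 3.52e-09. ARO3 went from 3193 ± 84.9 to 559.9 ± 36.3. In ergosterol synthesis, 21 of 23 fell and 1 rose. Their median was -2.26 (log2 change), with adjusted p = 4.55e-07. ERG13 went from 2126 ± 85.7 to 201 ± 23.2. Among cell wall genes, 19 of 26 fell and 5 rose (19 and 6 adjusted over the list alone). Their median was -1.84 (log2 change), with adjusted p = 0.00296. The glucan synthase GSC2 rose (646 ± 31.6 to 4459.8 ± 192). Of proteasome genes, 26 of 31 fell and 2 rose. Their median was -1.30 (log2 change), with adjusted p = 1.92e-05. RPN7 went from 1729.8 ± 34.8 to 304 ± 16.9. Of tricarboxylic acid cycle genes, 11 of 15 fell and 2 rose. Their median was -0.86 (log2 change), with adjusted p = 0.0133. IDH2 went from 3306 ± 61.3 to 344 ± 37.4. For the cell cycle, 17 of 24 fell and 2 rose. Their median was -1.11 (log2 change, -1.02 with values under background set to it), with adjusted p = 0.0174, but adjusted p = 0.0872 with an estimated correlation, the call kept in 7 of 8 alternatives. The replication clamp POL30 went from 690.1 ± 136 to 43.5 ± 21.4. For mitochondrial ribosomal proteins, 42 of 56 fell and 3 rose (42 and 4 adjusted over the list alone). Their median was -1.32 (log2 change, -1.2 with values under background set to it), with adjusted p = 3.26e-05, but adjusted p = 0.0981 with an estimated correlation, the call kept in 7 of 8 alternatives.

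SIP18 was at least 198-fold, SHH3 at least 159-fold and CRC1 at least 158-fold higher, and SPG1 (51.9 ± 7.52 to 14401 ± 1465) and SPG4 (63.3 ± 3.22 to 16163 ± 79.9), linked to survival in stationary phase, rose. HEM13 (at least 23.8-fold) and RCK1 (at least 6.51-fold) fell to background, and ERG1 (1523 ± 29.8 to 24.5 ± 13.6), PAN5 (745 ± 43.7 to 15.2 ± 13.0) and FKS1 (778 ± 60.3 to 19.5 ± 20.2, its brightest other probe set changing by -1.87) fell. HSP12 rose by 2.26 ± 0.24, HSP26 by 3.28 ± 0.09, GRE1 by 7.80 ± 0.22 and TPS1 by 0.37 ± 0.09, while TPS2 (-1.78 ± 0.18), HSP104 (-0.89 ± 0.13) and STF2 (-0.72 ± 0.12) fell. The tested ACT1 probe set changed by 1.26 ± 0.09, while its control probe sets went from 5709.7 ± 411 to 1029 ± 43.7 (5'), 4738 ± 158 to 1221 ± 99.4 (middle) and 4591 ± 182 to 5154 ± 376 (3'). CTT1 rose by 0.53 ± 0.20, though not without control replicate 1 or 2 or 360 min replicate 3 (0.39 without the last). In all, 6499 of 9275 probe sets changed, 3123 higher and 3376 lower (48.1% higher), with a median log2 change of -0.01 over all probe sets. The ACT1, SPT15 and SRB4 3' to 5' ratios were 2.63, 1.12 and 1.32 higher than in the control (log2, exact permutation p = 0.1 for each), and scan day cannot be told apart from group. Rescaling on the dimmer probe sets gave 3966 higher and 2609 lower (60.3% higher) and spike-in scaling, a shift of -2.32, 410 higher and 7521 lower (5.17% higher). With that shift the glyoxylate and fatty acid oxidation medians stay above 0 and those of autophagy, general stress and nitrogen-repressed genes are below it, as is HSP12.

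Whether rehydration undid the drying change was asked across probe sets, which are not independent replicates. The change from control to 18 h and that from dry to 360 min, which share no arrays, had a slope of -0.13 and a Pearson correlation of -0.17 (Spearman -0.17). Of 3358 probe sets that rose on drying, 1805 fell by 360 min, against 1366 for independent calls, and 675 rose again. Of 2536 that fell on drying, 704 rose, against 539, and 985 fell again. These counts depend on the scaling: those that fell after rising and rose after falling were 1380 (973 for independent calls) and 988 (728) with quantile normalization, and 1009 (722) and 1228 (1034) with median centring. They were 2111 (1973) and 25 (20.5) with spike-in scaling, and 1817 (1387) and 723 (523) after rescaling on the dimmer probe sets.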

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

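The chip carries control probe sets for ribosomal RNA, which the comparisons leave out, and 20 single-array signals from 5 of them were over 10 times the highest control array. For the first 25S probe set, against at most 355.2 in the control, the signals were 4921 in dry replicate 2, 5676, 5242 and 7282 at 15 min, 5771, 7732 and 9008 at 45 min, 8073, 4512 and 6617 at 90 min, and 6139, 9175 and 9464 at 360 min, in the order of the replicates. For another 25S probe set, against at most 577, they were 6803 and 8823 in replicates 1 and 3 at 15 min and 6454 and 6113 in replicates 2 and 3 at 45 min, while the 3 arrays of 360 min had 404.5, 206.5 and 384. Replicate 2 of 90 min, the array scanned alone on day 4, had 9912 for an 18S probe set, against at most 61.7, and 593 and 319 for other 25S probe sets, against at most 29.6 and 2.1. No explanation of these signals was tested. The groups hold 3 arrays, so single arrays were not tested as outliers within them.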

How the results depend on the processing

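Added after the data were seen were spike-in scaling, rescaling on the dimmer probe sets, leaving out the 90 min array scanned apart, the fits within 1 scan day, and the 20th percentile floor for the reversal. Over all alternatives run, 200 of 212 counts stayed within 1.5 times the reported one and 12 did not. With a change of at least 2-fold required, which by construction lowers a count, the counts were 3880 at 18 h against control, 1321 for dry against 18 h, 1162, 1198, 1636 and 3520 at 15, 45, 90 and 360 min against dry, and 984 for 360 against 90 min. With spike-in scaling they were 2418 for dry against 18 h, 5924, 5914 and 7142 at 15, 45 and 90 min against dry, and 6019 for 360 against 90 min. This scaling adds the spread of 9 probe sets to all genes of an array and moves them together. It does not show whether the amount of RNA per cell changed.

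Leaving out 1 array in turn gave 5526 to 5689 changed at 18 h, 3169 to 3288 for dry against 18 h, 5897 to 5980 for dry against control, 2974 to 3462, 3102 to 3461, 3603 to 4029 and 5336 to 5479 at 15, 45, 90 and 360 min against dry, 3083 to 3197 for 360 against 90 min and 6171 to 6318 for 360 min against control. The F test gave 7606 to 7825, and the correlation of the rehydration with the drying change -0.17 to -0.18, with slopes of -0.13. That relation had a slope of -0.12 without dim probe sets, r -0.22 and slope -0.16 with quantile normalization, and r -0.19 and slope -0.14 with the 20th percentile floor.

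The scalings moved the median of all genes. By more than 0.1 in log2, quantile normalization moved it by -0.11 and -0.20 at 18 h and dry against control, and by 0.18, 0.18, 0.22 and 0.26 at 15, 45, 90 and 360 min against dry. Median centring moved it by -0.15 at 18 h, -0.17 for dry against 18 h, -0.32 for dry against control, 0.38, 0.41, 0.41 and 0.52 in the same 4 rehydration comparisons, 0.11 for 360 against 90 min and 0.20 for 360 min against control. Rescaling on the dimmer probe sets moved it by 0.25 and 0.23 at 18 h and dry against control, 0.13, 0.15, 0.17 and 0.18 on rehydration and 0.36 for 360 min against control. The 20th percentile floor moved it by -0.11 and -0.23 at 18 h and dry against control and by 0.12, 0.11, 0.13 and 0.17 on rehydration. Adding 50 before log2 moved it by -0.13 for dry against control and 0.11 and 0.14 at 90 and 360 min against dry, and leaving out dim probe sets by 0.13 at 18 h and -0.15 at 360 min against dry.

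Of 10245 alternative values for named genes, 9875 kept their side of the threshold with no change of sign in a called value, 280 fell under it, 69 passed it and 21 changed sign with a call before or after. Changes of sign in all numbered 72, the other 51 without a call. All 21 came from quantile normalization or median centring, which move the median, and the cause was not tested further. Spike-in scaling and rescaling on the dimmer probe sets are not among these values, their named genes having been checked for sign only. Rescaling turned 0 of the called values. Spike-in scaling turned 9 of 19, 7 of 22, 10 of 21 and 17 of 34 called rises at 15, 45, 90 and 360 min against dry, 8 of 21 for 360 against 90 min and 7 of 35 for 360 min against control, and no others. The 21 were, with quantile normalization, HSP26 (-0.068, -0.0056 and -0.32 at 15, 45 and 90 min against dry), HXT5 (-0.074 at 15 and -0.072 at 360 min), ICL1 (-0.39, -0.44 and -0.59 at 15, 45 and 90 min), CTA1 (-0.069 at 45 min), ACT1 (-0.12), CIT2 (-0.27) and TPS1 (-0.26) at 90 min, and SIP18 (-0.31 at 360 min). With median centring the others were ACT1 (0.29) at 15 min, STF2 (0.026 at 15 and 0.093 at 45 min), HSP104 (0.018 at 45 min), FBP1 (0.38 at 90 and 0.36 at 360 min), and HSP26 (0.023) and TPS1 (0.52) at 360 min.

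Of 4041 alternative values for list tests, 3926 kept their call with no turn of a called direction, 63 lost the call, 47 gained it and 5 turned the direction of the test with a call before or after. Medians of opposite sign numbered 179, of which 173 had no called turn. The 5 were, with quantile normalization, general stress (-0.18), fatty acid oxidation (-0.058) and the tricarboxylic acid cycle (-0.22) at 45 min, the glyoxylate cycle (-0.16) at 90 min and fatty acid oxidation (-0.39) at 360 min, all against dry. Of 9342 alternative values for called changes of named genes, 375 lay over 1.5-fold from the reported one, 159 of them with log2(value + 50) and 92 with the 20th percentile floor. Of 270 list tests 87 were called with the preset correlation and 53 with an estimated one, and 34 calls were lost. The replicate number as a block gave 5864, 3590, 6222, 3672, 3762, 4164, 5728, 3405 and 6477 changes in the 9 comparisons in the order of the report, and 7763 by the F test. The numbers did not pair the arrays: over 63 pairs of like-numbered arrays the mean correlation of residuals was -0.00 (-0.13 to 0.09), 0 pairs were over 0.1, and 4 of 21 arrays were closest to their own number. Signal over background limits the folds of genes at background, which are given as lower bounds.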

Other observations

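The classes of RNA in this paragraph, and the tests on them, scan day, RNA quality and the highest signal below, were chosen after the values were seen. The rescaling was added then too, its test being fixed before its result was seen, while the splits were chosen before. Genes encoded in mitochondrial DNA and small nucleolar RNAs, which yeast cells make without a long poly(A) tail, were higher after rehydration with the deposited scaling. Of 19 mitochondrially encoded genes, 13 rose and 0 fell at 15 min against dry (median log2 change 1.15), 15 and 0 at 45 min (1.17), 18 and 0 at 90 min (1.88) and 18 and 0 at 360 min (2.41, adjusted p = 0.0195 with an estimated correlation). They include COB and COX1, the genes of cytochrome b and a cytochrome oxidase subunit. Between control and 18 h, 14 rose and 0 fell (1.86, adjusted p = 0.219 with an estimated correlation), and from 18 h to dry 1 rose and 9 fell (-0.74, adjusted p = 0.243 with an estimated correlation). Of 57 small nucleolar RNAs, 26 rose and 1 fell at 15 min (0.66), 25 and 1 at 45 min (0.52), 43 and 1 at 90 min (1.21) and 52 and 0 at 360 min (1.90), while 10 rose and 15 fell at 18 h against control (-0.20) and 3 rose and 24 fell from 18 h to dry (-0.62, adjusted p = 0.0628 with an estimated correlation). With spike-in scaling the nucleolar medians were -0.07, -0.20, 0.16 and -0.11 at 15, 45, 90 and 360 min, and the mitochondrial ones 0.42, 0.45, 0.83 and 0.41.

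One explanation of the mitochondrial rise is a larger share of RNA without a poly(A) tail in the labelled target. It predicts that small nucleolar RNAs rise too, and their median at 360 min against dry was 2.19 above that of all probe sets. That prediction was written after rises of such RNAs were seen, so it cannot decide, and the explanation stays open. Relative to all probe sets, the mitochondrial and nucleolar medians were 1.75 and -0.31 at 18 h against control. From 18 h to dry they were -0.80 and -0.68. Ribosomal RNA went both ways: from dry to 360 min one 25S probe set went from 2962 ± 1906 to 8259 ± 1842 and another from 2716 ± 2361 to 332 ± 109, below its control mean of 380.3. Scan day was argued against, since at 15 and 45 min, scanned on the same day as the dry arrays, the lower median was still 1.33 above that of all probe sets. A general rise of respiratory genes, the biological explanation tested, was argued against too, the nuclear respiratory genes being at -0.94 relative to all probe sets.

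More probe sets were called lower than higher in each of the 4 comparisons of rehydration with dry, from 30.3% to 34.3% higher. The authors' scaling, if pulled by the brightest probe sets, could give such a split. After rescaling on the dimmer probe sets the lowest share higher among the 4 comparisons was 42.2%, while spike-in scaling gave 1.27%, 1.57%, 1.27% and 0.819%, so the split depends on the scaling and its cause stays open. RNA quality cannot be told apart from it: the dry arrays, with ACT1 and SRB4 3' to 5' ratios above the control's and an SPT15 ratio below, had 59.6% higher than control, or 66.8% with the same rescaling, which moved 18 h against control from 57.0% to 65.9%. No biological explanation was tested.

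The highest signal on an array rose from 6396 ± 184 in the control to 24905 ± 752 at 360 min (mean ± SD, n = 3), and the share of signal in the brightest 1% of probe sets from 9.14% to 20.2%. An upper limit of the scanner, moved by the scaling, would tie the highest signal to the spike-in signal within time points. The slope was 0.39 (permutation p = 0.0300, 100000 permutations), with 0.22 to 0.56 when 1 array is left out, which is neither near 0 nor near 1, so this explanation cannot be told apart from others. Scan day alone, in a test also chosen after the values were seen, was argued against by a ratio of 1.79 between time points of scan day 2. No biological explanation was tested.

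Of 100 splits of the 21 arrays into 7 groups of 3, only the real one reached 7813 changes by the F test. The highest other gave 3837, which excludes random labels but not culture or scan day effects. For each of the 9 comparisons, 1 of 10 splits of 6 arrays, the real one, was as large, too few for a share under 0.05. The real counts and the highest others were 5894 and 1 at 18 h against control, 3633 and 1 for dry against 18 h, 6239 and 1 for dry against control, 3737 and 1, 3816 and 2, 4238 and 4, and 5743 and 1 at 15, 45, 90 and 360 min against dry, 3471 and 6 for 360 against 90 min, and 6499 and 4 for 360 min against control.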
